A study of Mus musculus with 14 samples.

How the data were processed

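RNA was measured in 14 libraries of sorted mouse leukemic stem cells in 5 groups. Before the sort they had grown, per the labels' protocols, in IMDM containing thrombopoietin (20 ng/ml), stem cell factor (50 ng/ml) and serum at 15%. Total RNA was extracted and made into Illumina libraries, per the labels' protocols. Strand handling, read length and the gene annotation are not given in the sources used here. The submitters' processing notes name CASAVA 1.8, TopHat and Cufflinks and the mouse build mm9. The reference at hand was of a later build, so no coordinates are given and genes are identified by the symbols in the files.

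The deposited FPKM values were made by the authors from aligned fragments with the tools above, per the submitters' processing notes, 1 file per library with 24463 gene symbols and none repeated. Of these genes 5406 were at 0 in every library. No scaling between libraries beyond FPKM is recorded. The values still hold whole reads: in each of the 19057 genes with reads, every library's FPKM was a whole multiple of 1 read's worth (100% of genes, within 0.0001 of a read). This gave library totals of 31.3 to 33.8 M reads for untreated cells and 19.0 to 22.7 M for treated cells, of which 59.0% to 61.1% lay in genes. It also gave whole gene lengths for 99.99% of 12716 genes (within 0.001). How reads shared between near-identical genes were counted is not given in the sources used here. Gapdh averaged 2.96 FPKM and Rps6 6.90, against 1121 for Actb, so genes with many pseudogene copies or close paralogs (Gapdh, ribosomal proteins, globins, stefins) are uncertain. Counts of reads recovered for a gene cover counting error only.

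Groups were taken from the sample titles. The genotype field went against the title for dKO replicate 1 and DMSO replicate 1. Two-sided tests were run with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend) on log2(FPKM + 1), for genes with a mean of at least 1 FPKM over the libraries of the fit, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 6 untreated libraries were 1 fit (dKO against WT). The 8 treated libraries were another (PGE1 and PGE2 against DMSO and against each other), since PGE2 has 2 libraries and shares the estimate of spread. Log2 differences are on the log2(FPKM + 1) scale, which understates changes of low genes; folds given with FPKM are ratios of group means. For some genes at or near 0, levels are given in place of a fold. The deleted genes were to be tested in the same limma fit, but both lay below its minimum level, so a two-sided exact permutation test on FPKM took its place. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the remaining steps.

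Before the data were examined, 30 gene lists with 489 entries (482 distinct genes, 7 of them in more than 1 list) were fixed, along with the tests, the alternatives and the rule for named genes. The lists covered AP-1 and other immediate early genes, cAMP and CREB targets, prostanoid genes, Tcf/Lef and Wnt genes, stem cell and homing genes, 8 sets of markers of other cell types (neutrophil, monocyte, mast cell, erythroid, megakaryocyte, B lymphoid, T and NK cell, dendritic cell with MHC class II), stromal and endothelial markers, cell cycle, p53, BCL2, STAT5, interferon, NF-kB, heat shock, unfolded protein, cholesterol, glycolysis, oxidative phosphorylation, ribosomal and sex-linked genes. Lists with at least 4 genes tested went through limma's cameraPR, on the moderated t statistics turned into z scores, with a preset inter-gene correlation of 0.01, adjusted over the 28 lists tested in a comparison. This test asks whether a list's genes moved more than other genes. No list passed in any of the 4 comparisons with camera at an estimated correlation (0 lists), and that adjusted p is given beside each call. The fry test, which asks whether a list's genes move on balance in 1 direction without comparing them with other genes, was run beside these.

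Named genes were Tcf7, Lef1 and Ptger1 to Ptger4; the 10 largest rises and 10 largest falls per comparison (5 and 5 for PGE1 against PGE2) among genes past the threshold with at least 5 FPKM in the higher group and no overlap between libraries, clone-type symbols left out; and up to 4 members with the smallest p of each list that passed and of the AP-1, immediate early, cAMP, Wnt and stem cell lists. Members that ran against their list, and those counted alone in one, were named after their values were seen, as were the genes of the DMSO against WT comparison. Some genes the rule names are not reported here.

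Fits were tested on simulated reads with real gene means and depths, 1 typical spread for all genes per comparison and 200 changed genes. Real genes vary more unevenly, so recovery is an upper guide. For dKO against WT (10703 genes) 100% of changed genes were recovered at 1.5-fold, 2-fold and 4-fold, and 21 of 240 calls (8.8%) were false. For PGE1 against DMSO (11240 genes) recovery was 97.0%, 95.5% and 98.5%, with 12 of 225 calls false (5.3%). For PGE2 against DMSO (11249 genes) it was 95.5%, 98.5% and 100%, with 16 of 230 false (7.0%). For PGE1 against PGE2 (11245 genes) it was 92.5%, 97.0% and 100%, with 8 of 221 false (3.6%). Of 200 random lists per comparison 1, 1, 1 and 2 had p below 0.05, but lists of correlated genes were not tried.

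Alternatives were pseudocounts of 0.1 and 5, no filter and a minimum of 5 FPKM, quantile normalization, median-of-ratios scaling, eBayes without trend or robust, library weights, all 14 libraries in 1 fit, the replicate number as a block, an added fold of at least 1.5, and each library left out in turn. For the lists and signatures they also included the other set tests and signatures of 100 genes. Where leaving out a PGE2 library leaves 1, that library is assumed to vary like the other groups. A pair of alternatives was added after seeing the data: limma-voom on the recovered reads, and averaging of libraries that differed least (the 3 WT libraries as 1 sample, DMSO replicates 2 and 3 as 1, and the PGE2 libraries as 1). Every replicate pair differed by more than counting noise, but technical spread can give this too, so it does not show that replicates were independent. Each library was counted as 1 replicate in the results.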

Results

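The samples were mouse leukemic stem cells (LSCs), the cells that sustain a leukemia, here from a model of chronic myeloid leukemia. Lineage-negative bone marrow cells were transduced 2 times, 24 h apart, with a retrovirus that carries p210 BCR-ABL, the fusion kinase of that disease. The LSCs were sorted as lineage-negative, c-Kit-positive, Sca1-positive and GFP-positive cells 48 h after isolation of the marrow. Transcript levels were given as FPKM (fragments scaled to the length of the gene model and to library depth) for 24463 genes in each of 14 libraries. Untreated cells came from wild-type marrow (WT, n = 3) or from marrow that lacked Tcf1 and Lef1 (dKO, n = 3). Tcf1, encoded by Tcf7, and Lef1 are DNA-binding partners of beta-catenin in the Wnt pathway. Control LSCs were treated for 6 h with vehicle (DMSO, n = 3), with 20 µM prostaglandin E1 (PGE1, n = 3) or with 20 µM prostaglandin E2 (PGE2, n = 2).

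The untreated libraries were deeper than the treated ones. Reads in genes ran from 19.2 to 19.9 M in WT and from 19.0 to 20.6 M in dKO. They ran from 12.6 to 13.4 M after DMSO, from 11.6 to 13 M after PGE1 and from 11.3 to 13 M after PGE2. No label said that replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. Replicates differed by more than counting noise in every group. Among genes with 1000 to 10000 reads, the variance between 2 libraries was 2.13 to 3.02 times counting noise in WT and 1.98 times after PGE2. It was 1.86 times for DMSO replicates 2 and 3, against 15.10 and 17.45 for the pairs with DMSO replicate 1. The pairs with PGE1 replicate 2 stood at 45.76 and 48.09, and the other PGE1 pair at 12.32. Pairs with dKO replicate 1 stood at 15.99 and 14.93, and the other dKO pair at 5.33.

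Tcf7 was at 1.31 ± 0.167 FPKM in WT (SD, n = 3; 345 reads in all) and at 0.0997 ± 0.0674 FPKM in dKO (n = 3; 26 reads), 7.6% of the WT level. Lef1 was at 0.283 ± 0.0524 FPKM in WT (101 reads) and 0.151 ± 0.0411 FPKM in dKO (54 reads), 53.5% of WT. Neither gene overlapped between the groups (two-sided exact permutation p = 0.1 for each, n = 3 against 3, the smallest p this design allows). Both lay below the minimum level for limma. Which exons were removed is not given in the sources used here, so the reads left in dKO may lie outside them. The library labelled dKO replicate 1 carries a wild-type genotype field and DMSO replicate 1 a Tcf1/Lef1-deficient one, against their titles. Tcf7 in both went with the titles, which set the groups here.

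Sex-linked genes also separated the genotypes. Ddx3y, Eif2s3y, Kdm5d and Uty, all on the Y chromosome, were listed at 0 in all 3 dKO libraries. In WT they stood at 8.45 ± 0.646, 16.1 ± 1.94, 2.31 ± 0.0822 and 2.10 ± 0.148 FPKM (n = 3 each), and Ddx3y stood between 6.49 and 9.64 FPKM in the libraries of the DMSO, PGE1 and PGE2 groups. Xist, the RNA that silences an X chromosome in females, was at 21.9 ± 8.29 FPKM in dKO and 10.1 ± 0.385 FPKM in WT. Every WT and treated group therefore carried both Xist and Y-linked reads. All 5 genes were also called after PGE1 against DMSO (adjusted p from 0.00672 to 0.0362). Eif2s3y (22.2 against 16.5 FPKM), Uty (3.28 against 2.12), Kdm5d (3.18 against 2.12) and Ddx3y (9.06 against 7.35) were higher, and Xist was lower (5.95 against 10.5). Leaving out 1 library ended the calls of Kdm5d (up to 0.0508), Ddx3y (0.115) and Xist (0.054). All but Ddx3y (0.0778) differed the same way between PGE1 and PGE2, and none was called after PGE2 against DMSO. Any gene that differs between male and female cells is part of the dKO against WT comparison and may be part of those with PGE1.

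**Figure D1:**
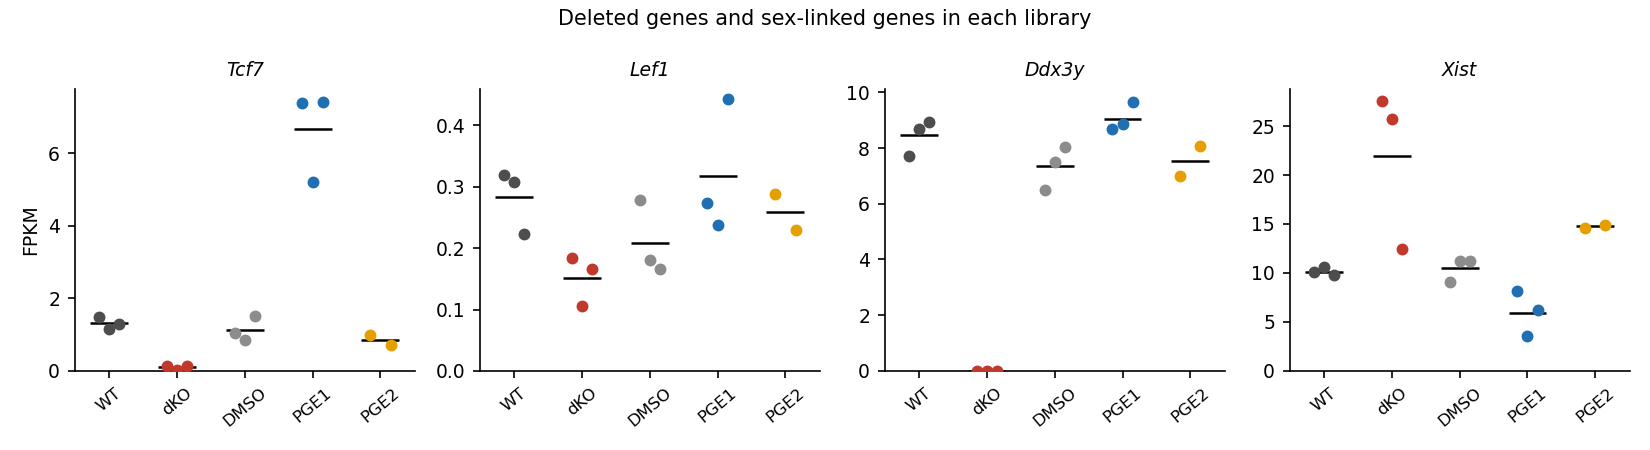
FPKM (linear axis from 0) of Tcf7, Lef1, Ddx3y and Xist in the 5 groups; each dot is a library and each line a group mean. Tcf7 averages 0.0997 in dKO against 1.31 in WT, and Ddx3y is at 0 in the 3 dKO libraries.

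The first comparison asked what differs in LSCs that lack Tcf1 and Lef1. Fosb and Fos showed the largest falls in dKO on the log2 scale. Fosb, an AP-1 subunit, was at 0.341 ± 0.256 FPKM against 105 ± 1.30 in WT, and Fos, its paralog, was 42.0-fold lower (3.68 ± 1.30 against 154 ± 3.15). Egr1, a serum-response transcription factor, was 15.5-fold lower (7.62 ± 3.84 against 118 ± 4.38). Lyz2, the lysozyme of macrophages, was 9.10-fold lower (49.9 ± 6.75 against 454 ± 13.6), and Ccl2, a monocyte chemokine, was 14.4-fold lower (1.0 ± 0.163 against 14.5 ± 0.510). Lipg, endothelial lipase, was 5.32-fold higher in dKO (56.6 ± 9.71 against 10.6 ± 0.762), while Xbp1, a transcription factor of the unfolded protein response, was 1.59-fold higher (185 ± 7.23 against 116 ± 4.28). Errors are SD, n = 3 per group.

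Of 10721 genes tested with limma, 4381 differed at an adjusted p below 0.05, 1930 of them higher and 2451 lower in dKO. Larger changes ran mostly downward, with 17 genes higher and 371 lower by at least 2-fold on the log2(FPKM + 1) scale. The split of directions depended on scaling and on the minimum level: 44.1% of the genes called were higher in dKO on the FPKM as deposited, 60.2% after quantile normalization and 56.2% after median-of-ratios scaling. It was 54.7% with a minimum of 5 FPKM and 35.2% with no filter. The 3 WT libraries lay close together; with their mean used as 1 sample, an alternative chosen after seeing the data, 768 genes were called, 21.9% of them higher. Libraries did not overlap between groups for 5882 genes (54.9%), against the 10% that chance gives for 3 against 3.

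AP-1 subunits and other immediate early genes were lower in dKO as groups. Of 10 AP-1 subunits tested, 8 fell, 0 rose and 2 did not pass (the same when adjusted over the list alone), with a median log2 difference of -1.24 (set test adjusted p = 9.99e-05; adjusted p = 0.347 with an estimated correlation). The log2 difference was -6.32 (SE 0.13, adjusted p = 1.27e-07) for Fosb and -5.09 (SE 0.18, adjusted p = 1.15e-06) for Fos. Jund fell 4.42-fold (37.6 ± 9.96 against 166 ± 3.91) and Fosl2 2.66-fold (2.15 against 5.74). Of 16 immediate early genes outside AP-1, 11 fell and 3 (Srf, Myc and Gadd45b) rose (12 and 3 adjusted over the list alone; median -0.77, set test adjusted p = 0.00225, adjusted p = 0.347 with an estimated correlation). Dusp1, a phosphatase of MAP kinases, fell 5.74-fold (3.27 ± 1.21 against 18.7 ± 0.622), Zfp36, which destabilises cytokine mRNAs, 4.94-fold (8.30 ± 2.49 against 41.0 ± 1.92) and Klf4 3.25-fold (1.40 against 4.54). NF-kB and inflammatory genes went the same way, with 13 of 15 lower and 1, Tnfaip2, higher (also over the list alone; median -0.68, set test adjusted p = 8.37e-05, adjusted p = 0.347 with an estimated correlation). Among them Tnfaip3, an inhibitor of NF-kB, fell 2.77-fold and Icam1, an adhesion molecule, 1.71-fold, and Cxcl3, a neutrophil chemokine, stood at 0.163 FPKM in dKO and 5.03 in WT. Of 15 interferon-response genes, 10 fell and 0 rose (11 over the list alone; median -0.31, set test adjusted p = 1.65e-05, adjusted p = 0.272 with an estimated correlation), among them Irf7 (1.83 ± 0.358 against 6.55 ± 0.251), Rtp4 (4.38-fold) and Oasl2 (4.25-fold).

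Marker lists of 5 blood lineages passed as lower in dKO. Of 16 monocyte and macrophage markers 15 fell and 0 rose, the same over the list alone (median -1.73, set test adjusted p = 2.57e-11, adjusted p = 0.0846 with an estimated correlation). With Lyz2 (adjusted p = 4.87e-07), Ctss, a lysosomal protease, fell 8.47-fold (15.8 ± 0.586 against 134 ± 4.38), Mpeg1 6.85-fold and Cd68 4.74-fold. All 12 megakaryocyte markers fell, also over the list alone (median -0.95, set test adjusted p = 2.54e-05, adjusted p = 0.347 with an estimated correlation), among them Treml1 (4.46-fold), the tetraspanin Cd9 (2.30-fold) and the integrin Itgb3 (2.25-fold). Of 5 dendritic cell and MHC class II genes 4 fell and 0 rose, as over the list alone (median -1.48, set test adjusted p = 9.43e-04, adjusted p = 0.347 with an estimated correlation), such as Cd74, the invariant chain (21.3 ± 5.57 against 59.9 ± 3.53), and H2-Aa (6.76 ± 1.35 against 21.1 ± 0.948). Of 9 mast cell and basophil markers 6 fell and 0 rose, as over the list alone (median -0.39, set test adjusted p = 0.00256, adjusted p = 0.347 with an estimated correlation), including Hdc, which makes histamine (2.05-fold), and the proteases Prss34 (3.24-fold) and Gzmb (3.89-fold). Of 12 erythroid markers 9 fell and 1 rose, as over the list alone (median -0.60, set test adjusted p = 0.00943, adjusted p = 0.347 with an estimated correlation). The transferrin receptor Tfrc was the one that rose (132 ± 1.34 against 87.7 ± 4.06, 1.5-fold), and Hbb-b1, a globin whose reads can be shared with its copies, was 2.54-fold lower. The erythroid set call was lost with a minimum mean of 5 FPKM (adjusted p = 0.0754).

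The neutrophil list went both ways: 8 of 17 rose and 5 fell (9 and 5 over the list alone; set test adjusted p = 0.165), with a median of 0.16 and a mean of -0.23. The late granule genes Ltf, Camp, Mmp8, Lcn2 and Ngp were the ones that fell. B lymphoid markers, 3 (Vpreb1, Vpreb3 and Igll1) higher and 2 (Il7r and Blnk) lower of 8, as over the list alone, had a median of 0.05 (set test adjusted p = 0.981). T and NK cell markers had 3 members tested and stromal and endothelial markers 1, too few for a set test. The sex-linked list, with Xist higher and the 4 Y-linked genes lower, as over the list alone, passed its set test beside all of these lists (median -1.73, adjusted p = 9.43e-04, adjusted p = 0.272 with an estimated correlation).

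Haematopoietic stem cell genes and homing genes were lower in dKO as groups. Of 16 stem cell genes 10 fell and 0 rose, the same over the list alone (median -0.42, set test adjusted p = 0.00186, adjusted p = 0.347 with an estimated correlation). Cd34, a progenitor surface protein, fell 1.81-fold (36.1 ± 1.45 against 65.4 ± 1.59, adjusted p = 6.59e-06), Flt3, a progenitor cytokine receptor, 3.01-fold (1.83 against 5.50), Meis1 1.59-fold (4.33 against 6.89) and Cdkn1c, a cell cycle inhibitor, 6.64-fold (0.287 against 1.91). Of 14 homing and adhesion genes 10 fell and 1 rose, as over the list alone (median -0.43, set test adjusted p = 0.00208, adjusted p = 0.347 with an estimated correlation). Cxcr4, the receptor that holds stem cells in marrow, was the one that rose (63.3 ± 2.75 against 46.7 ± 1.16, 1.36-fold), while Cd93, Itgal and Itga5 fell (33.6 against 50.3, 25.3 against 32.5 and 6.90 against 11). Of 6 Tcf/Lef family and Wnt target genes 3 fell and 1 rose, as over the list alone (median -0.07, set test adjusted p = 0.355). The cyclin Ccnd1 fell 2.14-fold (4.06 ± 0.651 against 8.69 ± 0.490, adjusted p = 2.71e-04) and Cd44 1.44-fold (27.9 against 40.3). Myc rose 1.23-fold (123 ± 4.38 against 100 ± 1.62, adjusted p = 8.22e-04), and beta-catenin itself, Ctnnb1, fell 1.08-fold (adjusted p = 0.0434), a call lost without WT replicate 1 (adjusted p = 0.11), WT replicate 2 (0.0999), WT replicate 3 (0.147) or dKO replicate 2 (0.117) and after median-of-ratios scaling (0.228). Of 12 cAMP and CREB targets 4 fell and 1 rose, as over the list alone (median -0.08, set test adjusted p = 0.247), among them Rgs2, a regulator of G protein signalling, 2.32-fold lower, and Cited2, 1.51-fold higher (139 ± 4.81 against 92.0 ± 2.60). Of 11 genes of prostanoid receptors and metabolism 2 (Ptges2 and Ptges3) rose and 2 (Hpgds and Tbxas1) fell, as over the list alone (set test adjusted p = 0.854), with a median of 0.05 and a mean of -0.08. The receptor genes Ptger1 (21.4 against 21.8 FPKM, adjusted p = 0.656), Ptger3 (8.93 against 8.30, adjusted p = 0.15) and Ptger4 (1.97 against 2.50, adjusted p = 0.0799) did not pass, though Ptger4 passed without WT replicate 3 (adjusted p = 0.0339) and Ptger3 after quantile normalization (adjusted p = 0.0158). Ptger2 was below the minimum level, at 0.348 against 0.923 FPKM.

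Of 16 unfolded protein and amino acid stress genes 12 rose in dKO and 0 fell, the same over the list alone (median 0.44, set test adjusted p = 1.68e-06, adjusted p = 0.272 with an estimated correlation). Besides Xbp1 (adjusted p = 2.81e-05), Atf5 rose 1.63-fold, Sdf2l1 1.43-fold and Psat1 1.40-fold. Of 18 cholesterol synthesis genes 14 rose and 0 fell, as over the list alone (median 0.39, set test adjusted p = 7.06e-06, adjusted p = 0.347 with an estimated correlation), such as Fdps (50.2 ± 9.86 against 28.5 ± 0.997, 1.76-fold) and Mvd (1.69-fold). Of 16 G1/S genes 13 rose and 0 fell, as over the list alone (median 0.15, set test adjusted p = 7.37e-05, adjusted p = 0.272 with an estimated correlation), including Rrm2 (116 ± 7.46 against 83.3 ± 0.363, 1.39-fold), and Ccne1 (1.28-fold). The calls of 4 further lists depended on scaling. G2/M genes (6 of 16 higher, 0 lower; 7 higher and 1 lower over the list alone; median 0.09, set test adjusted p = 0.023, adjusted p = 0.347 with an estimated correlation) did not pass after quantile normalization (adjusted p = 0.524), with a minimum of 5 FPKM (0.105) or without WT replicate 1 (0.0606). Plk1, a mitotic kinase, rose 1.22-fold and Cdk1 1.17-fold. Heat shock genes (3 of 8 higher, 0 lower; 4 higher over the list alone; median 0.12, set test adjusted p = 0.0242, adjusted p = 0.347 with an estimated correlation) did not pass after quantile normalization (0.164) or with a minimum of 5 FPKM (0.0831); Hsp90aa1 rose 1.25-fold and Hspd1 1.28-fold. Ribosomal protein genes (9 of 30 higher, 1 lower; 5 and 1 over the list alone; median 0.11, set test adjusted p = 9.43e-04, adjusted p = 0.431 with an estimated correlation) did not pass after quantile normalization (0.974), where Rpl8 turned from higher to lower in dKO (log2 difference -0.231). Oxidative phosphorylation genes (5 of 15 higher, 0 lower, as over the list alone; median 0.10, set test adjusted p = 0.0079, adjusted p = 0.457 with an estimated correlation) did not pass after quantile normalization either (0.874), where the direction of their set test turned; Uqcrc1 rose 1.29-fold. Lists that did not pass were p53 targets (1 of 13 higher, 4 lower, as over the list alone; adjusted p = 0.228), BCL2 family genes (1 of 12 higher, 3 lower, as over the list alone; adjusted p = 0.981; median 0.05 and mean -0.05) and STAT5 targets and cytokine feedback genes (7 of 17 higher, 4 lower, 8 and 4 over the list alone; adjusted p = 0.0659), which passed without dKO replicate 2 (0.0137). Glycolysis and hypoxia genes did not pass either (5 of 15 higher, 1 lower, as over the list alone; adjusted p = 0.0536), but passed without WT replicate 3 (0.0377), dKO replicate 2 (0.00915) or dKO replicate 3 (0.0125).

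Gpnmb, a glycoprotein of macrophages, fell 19.5-fold in dKO (7.77 ± 0.709 against 152 ± 7.90), Apoe, a lipid carrier, 13.6-fold (14.2 ± 4.35 against 193 ± 8.67), Ppbp, a platelet chemokine, 15.2-fold (1.75 ± 1.28 against 26.8 ± 1.39; 26.2-fold without dKO replicate 1), Adam8, a surface protease, 12.5-fold (3.73 ± 2.28 against 46.6 ± 0.667; 19.3-fold without that library) and Emp1 18.5-fold (1.05 ± 0.437 against 19.4 ± 0.358). Rpl34-ps1, a ribosomal protein pseudogene whose reads can belong to its parent gene, stood at 11.8 against 151 FPKM. Among the rises, Cited4 was 4.76-fold higher (13.9 ± 4.58 against 2.92 ± 0.664), Cth 3.60-fold (17.3 ± 3.56 against 4.80 ± 0.252), G0s2 3.15-fold (20.2 ± 2.12 against 6.41 ± 0.312) and Myl10 2.78-fold (134 ± 13.8 against 48.2 ± 1.24). Serpina3g was 2.56-fold higher (68.8 ± 9.09 against 26.9 ± 1.67), the metallothionein gene Mt2 2.33-fold (39.2 ± 12.3 against 16.8 ± 1.04), Podxl 2.77-fold (5.99 against 2.16) and Tarm1 (6.84 against 2.63). Scd1, a fatty acid desaturase, was 3.82-fold higher (9.26 ± 5.98 against 2.43, adjusted p = 0.0189; 2.48-fold without dKO replicate 1), a call lost without WT replicate 1 (adjusted p = 0.0502), WT replicate 2 (0.0628), WT replicate 3 (0.0551) or dKO replicate 3 (0.0532).

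**Figure D2:**
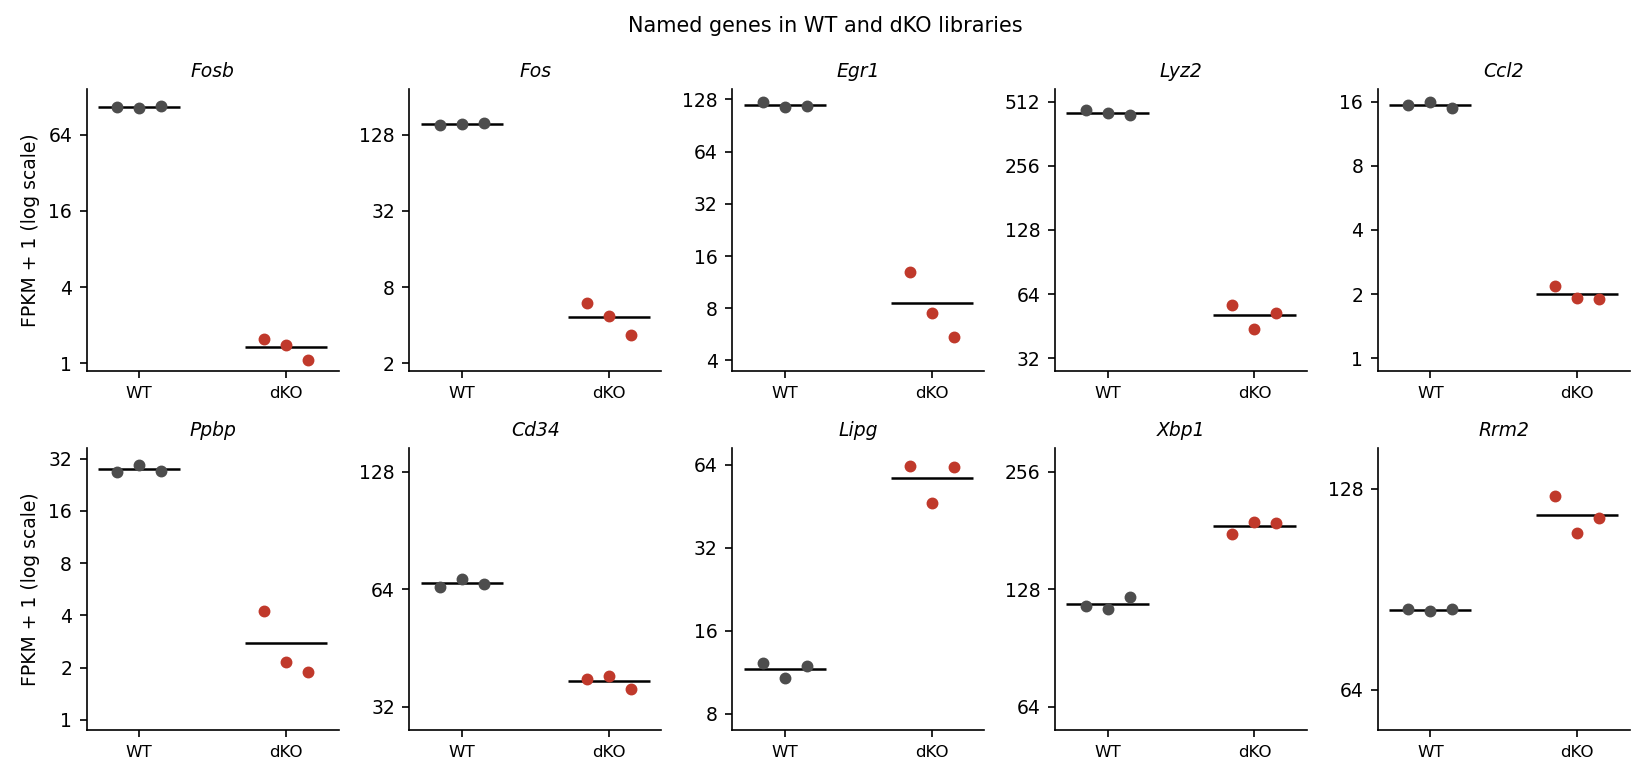
FPKM + 1 on a log2-spaced axis for 10 named genes in WT and dKO; each dot is a library (n = 3 per group) and each line a group mean. Fosb falls from 105 to 0.341 FPKM and Lipg rises from 10.6 to 56.6 FPKM, with no overlap between libraries.

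The second comparison asked what 20 µM PGE1 did to control LSCs in 6 h. Crem, a cAMP-responsive transcription factor, rose 6.64-fold (27.8 ± 6.20 against 4.18 ± 0.332 FPKM after DMSO), and the phosphodiesterase genes Pde3b and Pde4d, whose products degrade cAMP, rose 6.44-fold (20.3 ± 2.36 against 3.15 ± 0.455) and 6.27-fold (9.28 ± 1.0 against 1.48 ± 0.122). Fosb fell 140-fold (0.841 ± 0.0712 against 117 ± 8.53), Egr1 20.0-fold (4.60 ± 1.09 against 91.9 ± 12.6), Myc 4.93-fold (14 ± 6.67 against 68.8 ± 3.63) and Socs1, a feedback inhibitor of cytokine signalling, 9.16-fold (3.63 ± 0.841 against 33.2 ± 2.52). Tcf7 rose 5.86-fold (6.66 ± 1.25 against 1.14 ± 0.350, adjusted p = 3.68e-05). Errors are SD, n = 3 per group.

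Of 11242 genes tested, 5515 differed from DMSO at an adjusted p below 0.05, 2652 higher and 2863 lower. By at least 2-fold on the log2(FPKM + 1) scale, 260 were higher and 469 lower. Libraries did not overlap for 6427 genes (57.2%), against 10% by chance.

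Of 15 cAMP and CREB targets 10 rose and 2 (Cited2 and Per2) fell, the same over the list alone (median 1.05, set test adjusted p = 6.62e-04, adjusted p = 0.259 with an estimated correlation). Crem (adjusted p = 4.81e-06) was joined by Nr4a1, an orphan nuclear receptor, 3.17-fold higher (7.45 against 2.35). Among the E-type prostaglandin receptors, Ptger2, which couples to cAMP production, rose 3.64-fold (5.48 ± 0.446 against 1.5 ± 0.147, adjusted p = 9.20e-06) and Ptger3, which couples to its inhibition, fell 2.62-fold (3.04 ± 0.367 against 7.97 ± 0.112, adjusted p = 1.57e-05). Ptger1 rose 1.16-fold (33.0 ± 1.36 against 28.5 ± 0.698, adjusted p = 0.018), a call lost without DMSO replicate 2 (adjusted p = 0.0735). Ptger4 fell 1.38-fold (3.50 ± 0.680 against 4.83 ± 0.0414, adjusted p = 0.022), a call lost without DMSO replicate 1 (0.0539), 2 (0.061) or 3 (0.0609) or PGE1 replicate 1 (0.0517). Of 13 prostanoid receptor and metabolism genes 4 rose and 6 fell (5 and 7 over the list alone; median -0.29, set test adjusted p = 0.661).

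The AP-1 list split: 5 of 10 fell and 2 (Fosl2 and Jun) rose, as over the list alone (median -0.32, set test adjusted p = 0.16). Fosb (log2 difference -6.00, SE 0.07, adjusted p = 4.98e-10), Jund (57.2 ± 2.65 against 259 ± 25.9, 4.53-fold) and Atf3 (9.06 against 18.1) fell, and Fosl2 rose 3.81-fold (51.6 ± 2.83 against 13.6 ± 1.51). Of 16 other immediate early genes 10 fell and 2 rose (11 and 2 over the list alone; median -0.28, set test adjusted p = 0.0198, adjusted p = 0.508 with an estimated correlation). Egr1 (adjusted p = 2.79e-07), Klf2 (5.37-fold) and Dusp1 (2.34-fold) fell, while Btg2 rose 2.73-fold (23.0 against 8.43). STAT5 targets and cytokine feedback genes fell in 14 of 17 cases, with 1, Dusp6, higher, as over the list alone (median -1.04, set test adjusted p = 3.84e-06, adjusted p = 0.322 with an estimated correlation), including Socs3 (5.98-fold), Cish (4.92-fold) and Spry2 (2.41-fold). Of 7 Tcf/Lef family and Wnt target genes 4 fell and 1, Tcf7, rose, as over the list alone (median -0.49, set test adjusted p = 0.148). Ccnd1 fell 9.48-fold (0.713 ± 0.206 against 6.76 ± 0.382), Cd44 1.64-fold (37.9 against 61.9) and Myc with an adjusted p of 9.82e-05. Lef1 stayed below the minimum level, at 0.209 FPKM after DMSO and 0.318 after PGE1.

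Stem cell genes went both ways, 10 of 19 higher and 4 lower (11 and 4 over the list alone; median 0.38, set test adjusted p = 0.0587). Procr, the protein C receptor found on stem cells, rose 2.70-fold (58.9 ± 9.18 against 21.8 ± 0.824) and Meis1 2.22-fold (15.1 ± 1.12 against 6.83 ± 0.246), while Cd34 fell 2.11-fold (19.4 against 40.9) and Txnip 2.06-fold. Neutrophil markers fell in 16 of 18 cases, with 0 higher (17 lower over the list alone; median -1.08, set test adjusted p = 3.84e-06, adjusted p = 0.383 with an estimated correlation), among them the granule genes Camp (4.59-fold) and Fcnb (2.32-fold) and the transcription factors Gfi1 (2.90-fold) and Cebpa (41.8 against 98.8, 2.37-fold). Of 16 monocyte and macrophage markers 10 fell and 2 (Cd14 and Csf1r) rose (12 and 2 over the list alone; median -0.67, set test adjusted p = 7.63e-04, adjusted p = 0.383 with an estimated correlation). Adgre1 (5.17-fold), Irf8 (2.57-fold) and Mpeg1 (1.75-fold) fell, whereas Cd14, a co-receptor for lipopolysaccharide, rose 6.37-fold (297 ± 42.1 against 46.6 ± 1.63). Of 10 mast cell and basophil markers 6 rose and 2 (Gzmb and Prss34) fell (7 and 2 over the list alone; median 0.62, set test adjusted p = 0.0544, which passed without DMSO replicate 1 at 0.0381, DMSO replicate 2 at 0.0489 or PGE1 replicate 1 at 0.0312).

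G1/S genes fell in 11 of 16 cases and 0 rose (as over the list alone; median -0.41, set test adjusted p = 5.74e-04, adjusted p = 0.508 with an estimated correlation), with Ccne1 3.11-fold, Ccne2 1.88-fold, Cdc6 1.82-fold and Rrm2 1.79-fold lower. Of 13 p53 targets 9 rose and 1 fell, as over the list alone (median 0.50, set test adjusted p = 0.00272, adjusted p = 0.383 with an estimated correlation). Bbc3, which promotes apoptosis, rose 2.33-fold (31.6 ± 2.85 against 13.6 ± 0.768), Trp53inp1 3.15-fold and Sesn1 1.91-fold, and Aen fell 1.77-fold. Of 16 unfolded protein and amino acid stress genes 12 fell and 3 (Ddit4, Slc7a11 and Ddit3) rose, as over the list alone (median -0.51, set test adjusted p = 0.0176, adjusted p = 0.508 with an estimated correlation): the chaperone Hspa5 fell 1.92-fold, Pdia4 2.08-fold and Sdf2l1 2.92-fold, and Ddit4, an inhibitor of mTOR signalling, rose 4.42-fold (128 ± 11.8 against 29.1 ± 2.33). Of 17 cholesterol synthesis genes 13 rose and 0 fell, as over the list alone (median 0.50, set test adjusted p = 1.24e-04, adjusted p = 0.383 with an estimated correlation), such as Cyp51 (38.7 against 20.4 FPKM). Of 15 glycolysis and hypoxia genes 11 fell and 1 rose, as over the list alone (median -0.72, set test adjusted p = 0.00398, adjusted p = 0.508 with an estimated correlation), with Pfkp 2.20-fold, Pdk1 2.42-fold and Ndrg1 1.73-fold lower and Vegfa, an angiogenic growth factor, 2.27-fold higher (55.1 ± 4.19 against 24.3 ± 1.49).

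Other lists did not pass after PGE1. Counts adjusted over the list alone were the same except for 4 G2/M genes, 4 interferon genes, 9 NF-kB genes and 5 homing genes higher, 3 oxidative phosphorylation genes lower and 0 ribosomal genes higher. Set test adjusted p was 0.0517 for G2/M genes (5 of 16 higher, 0 lower), which passed without DMSO replicate 1 (0.0381) or PGE1 replicate 2 (0.00538), after quantile normalization (0.0482), with a pseudocount of 0.1 (0.0497) and with a minimum of 5 FPKM (0.0434). It was 0.148 for heat shock genes (0 of 10 higher, 5 lower), a list that passed without PGE1 replicate 2 (0.0207). Oxidative phosphorylation genes (0 of 15 higher, 5 lower; 0.16) passed without that library too (0.0207), and ribosomal protein genes (1 of 30 higher, 2 lower; 0.188) after quantile normalization (0.00913). The p was 0.168 for BCL2 family genes (7 of 14 higher, 2 lower), 0.188 for interferon-response genes (3 of 19 higher, 9 lower), 0.313 for NF-kB and inflammatory genes (8 of 20 higher, 11 lower) and 0.661 for homing and adhesion genes (4 of 14 higher, 6 lower). Erythroid (6 of 12 higher, 4 lower; 0.377), megakaryocyte (5 of 12 higher, 3 lower; 0.538), T and NK cell (1 of 4 higher, 1 lower; 0.608) and MHC class II lists (1 of 7 higher, 3 lower; 0.29) did not pass either. The sex-linked list (4 of 5 higher, 1 lower; 0.205) did not pass. B lymphoid markers had 3 members tested and stromal and endothelial markers 1, too few for a set test.

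Peg10 rose 25.3-fold (43.9 ± 6.05 against 1.73 ± 0.470, adjusted p = 5.82e-07), Ramp3 21.5-fold (46.5 ± 7.57 against 2.16 ± 0.432) and Dgat1 9.90-fold (149 ± 17.0 against 15.0 ± 1.49, adjusted p = 1.59e-07). Pdcd1, the PD-1 receptor, went from 0.447 ± 0.131 to 18.9 ± 2.56 FPKM, Gzmc, a granzyme, from 0.890 to 17.5 ± 5.35, Vgf from 0.652 to 11.7 and P2ry10 from 0.524 to 10.3. The transporter Cnnm2 rose 7.93-fold (27.3 ± 1.22 against 3.44 ± 0.0549) and Cables1 7.78-fold (27.2 against 3.49). Lpl, lipoprotein lipase, fell 47.4-fold (0.751 against 35.6 ± 2.45), Pgf, a placental growth factor, 50.8-fold (0.358 against 18.2) and Cxcl3 9.40-fold (6.45 ± 0.670 against 60.6 ± 3.05). Mmp13, a collagenase, fell 13.9-fold (1.52 ± 0.137 against 21.2 ± 1.99). Prg2, an eosinophil granule protein, fell 6.81-fold with a wide spread (8.43 ± 9.81 against 57.4 ± 6.07, adjusted p = 0.00738; 19.2-fold without PGE1 replicate 1). Mmp10, Stfa2 and Nov fell to near 0, at 0.0459, 0.113 and 0.324 FPKM after PGE1 and 19.9, 9.89 and 10.6 after DMSO; Stfa2 has near-identical copies that can share its reads.

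**Figure D3:**
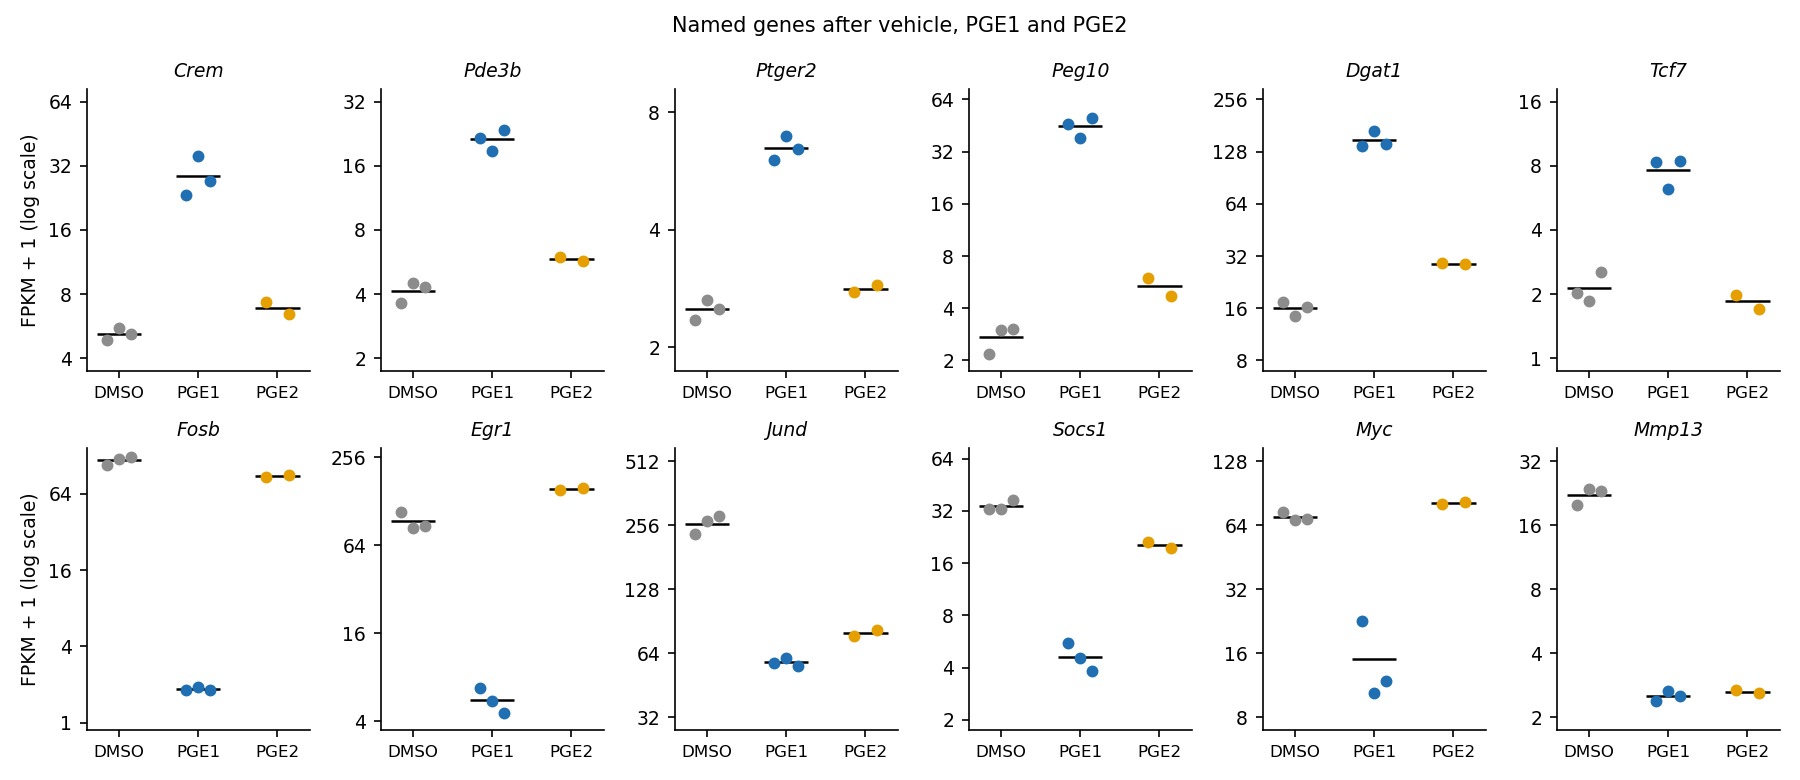
FPKM + 1 on a log2-spaced axis for 12 named genes after DMSO (n = 3), PGE1 (n = 3) and PGE2 (n = 2); each dot is a library and each line a group mean. Crem averages 4.18, 27.8 and 5.88 FPKM in that order, and Mmp13 21.2, 1.52 and 1.64 FPKM.

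The third comparison asked what the same dose and time of PGE2 did. The largest changes were falls. Mmp13 fell 13-fold (1.64 ± 0.0657 against 21.2 ± 1.99 FPKM after DMSO; SD, n = 2 against 3), Mmp10, a stromelysin, 16.8-fold (1.19 ± 0.308 against 19.9 ± 0.751), Perp 10.8-fold (3.12 ± 0.618 against 33.5 ± 2.06), the chemokine Ccl5 7.31-fold (3.20 ± 0.367 against 23.4 ± 1.16) and Spp1, osteopontin, 4.89-fold (130 ± 9.14 against 637 ± 5.46). Jund fell 3.29-fold (78.7 ± 3.25 against 259 ± 25.9, adjusted p = 3.79e-05). The largest rises included Cables1 (7.41 against 3.49, 2.12-fold, adjusted p = 0.00124) and Dgat1 (27.9 ± 0.406 against 15.0 ± 1.49, 1.86-fold, adjusted p = 0.00261).

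Of 11242 genes tested, 626 differed from DMSO, 112 higher and 514 lower, with 1 higher and 86 lower by at least 2-fold on the log2(FPKM + 1) scale. The share higher, 17.9%, was 24.8% with quantile normalization, 26.2% with median-of-ratios scaling, 35.8% with all 14 libraries in the fit, 50.1% (1899 higher, 1895 lower) with library weights. It ran from 3.2% to 29.4% with 1 library left out. The count depended on single libraries: 156 without PGE2 replicate 1, 125 without PGE2 replicate 2, 240 and 236 without DMSO replicates 2 and 3, and 1218 without PGE1 replicate 2, which shares the estimate of spread. It was 3794 with library weights, 1207 with all 14 libraries in the fit, 297 with an added fold of at least 1.5, and 55 when DMSO replicates 2 and 3 counted as 1 sample and the PGE2 libraries as 1. Libraries did not overlap for 5515 genes (49.1%), against 20% by chance for 2 against 3.

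Falls by size that held when any 1 library was left out, besides those above, were in Crisp1 (0.603 against 8.65, 14.3-fold), Tnfrsf11b, the osteoclast inhibitor osteoprotegerin (0.335 against 5.29, 15.8-fold), Pdpn (2.13 against 14, 6.55-fold), Uchl1 (6.20 against 33.1, 5.34-fold) and Stfa2 (1.16 against 9.89, 8.55-fold). NF-kB and inflammatory genes fell in 8 of 20 cases and 0 rose (12 lower and 1 higher over the list alone; median -0.35, set test adjusted p = 1.12e-06, adjusted p = 0.18 with an estimated correlation), including the chemokine genes Ccl4 (14 ± 1.46 against 59.5 ± 2.68, 4.25-fold) and Ccl3 (2.23-fold), and Nfkb2 (1.58-fold). Of 19 interferon-response genes 4 fell and 0 rose (14 lower over the list alone; median -0.39, set test adjusted p = 3.03e-07, adjusted p = 0.18 with an estimated correlation). Isg15, a ubiquitin-like protein, fell 2.38-fold (10.7 ± 1.19 against 25.4 ± 1.38, adjusted p = 0.00129), and Xaf1 (1.13 against 2.28), Oas1a (1.55-fold) and Stat2 (1.33-fold) were lower with calls lost without PGE2 replicate 1 (adjusted p = 0.119, 0.154 and 0.24) or PGE2 replicate 2 (0.229, 0.223 and 0.235).

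Of the 54 named genes called in this comparison, 33 lost the call without PGE2 replicate 1, 34 without PGE2 replicate 2, 24 without DMSO replicate 2 and 27 without DMSO replicate 3. Each further gene given here as changed after PGE2, with Dusp1, Dusp5 and Ier5 as exceptions, lost its call without at least 1 of them. Of 10 AP-1 subunits 3 fell and 1 rose (3 and 2 over the list alone; set test adjusted p = 0.942; median 0.10, mean and test below 0). Fos rose 1.89-fold (223 ± 14.1 against 118 ± 12.9, adjusted p = 0.00428), Fosb fell 1.33-fold (88.5 ± 2.27 against 117 ± 8.53, adjusted p = 0.0207) and Atf3 1.81-fold. Of 16 other immediate early genes 4 fell and 2 rose, as over the list alone (set test adjusted p = 0.322; median 0.01, mean -0.09). Dusp1 (1.94-fold), Dusp5 (1.73-fold) and Ier5 (1.84-fold) fell, while Egr1 rose 1.67-fold (153 ± 3.46 against 91.9 ± 12.6, adjusted p = 0.0314). Of 15 cAMP and CREB targets 3 rose and 1 fell (4 and 3 over the list alone; median 0.11, set test adjusted p = 0.322): Nr4a1 rose 1.75-fold (adjusted p = 0.00409), Pde4d 1.72-fold (adjusted p = 0.0274) and Pde3b 1.54-fold (adjusted p = 0.05, just under the threshold before rounding), and Plk2 fell 1.86-fold. Ptger4 fell (2.42 ± 0.290 against 4.83 ± 0.0414, adjusted p = 0.0105). Ptger1 (26.6 against 28.5, adjusted p = 0.461), Ptger2 (1.83 against 1.5, adjusted p = 0.357), Ptger3 (7.73 against 7.97, adjusted p = 0.864) and Tcf7 (0.845 ± 0.203 against 1.14 ± 0.350, adjusted p = 0.574) did not pass, and Lef1 stayed below the minimum level at 0.259 FPKM. Of 7 Tcf/Lef family and Wnt target genes 1 fell and 0 rose (median -0.17, set test adjusted p = 0.189): Cd44, 1.34-fold (46.3 against 61.9, adjusted p = 0.0152). Of 19 stem cell genes 1 fell and 0 rose (2 lower over the list alone; median -0.04, set test adjusted p = 0.781): Procr, 1.65-fold (13.2 ± 1.56 against 21.8 ± 0.824, adjusted p = 0.0148).

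Several lists passed the set test with few single genes called. G1/S genes had 1 of 16 higher and 0 lower (6 higher over the list alone; median 0.23, set test adjusted p = 7.94e-07, adjusted p = 0.351 with an estimated correlation), namely Tk1, thymidine kinase (21.7 against 13.8, adjusted p = 0.0457). G2/M genes had 0 of 16 called (3 higher over the list alone; median 0.16, set test adjusted p = 3.79e-04, adjusted p = 0.303 with an estimated correlation). Neutrophil markers had 1 of 18 higher and 0 lower (5 and 1 over the list alone; median 0.50, set test adjusted p = 2.58e-05, adjusted p = 0.389 with an estimated correlation), namely Ngp (338 ± 17.0 against 216 ± 24.2, adjusted p = 0.0458). Monocyte and macrophage markers had 2 of 16 higher and 1 lower (8 and 1 over the list alone; median 0.32, set test adjusted p = 3.47e-04, adjusted p = 0.303 with an estimated correlation): Mpeg1 rose 1.36-fold (adjusted p = 0.0039), Cd14 rose 1.52-fold (adjusted p = 0.0177) and Cx3cr1 fell 2.02-fold. Of 13 p53 targets 3 fell and 0 rose (5 lower over the list alone; median -0.18, set test adjusted p = 0.0015, adjusted p = 0.303 with an estimated correlation), including Bbc3 (9.48 against 13.6, 1.43-fold) and Mdm2 (1.31-fold). Cholesterol synthesis genes had 4 of 17 higher and 0 lower (10 higher over the list alone; median 0.22, set test adjusted p = 7.12e-07, adjusted p = 0.262 with an estimated correlation), such as Mvd (1.37-fold) and Nsdhl (1.35-fold). Glycolysis and hypoxia genes had 2 of 15 higher and 1 lower (8 and 1 over the list alone; median 0.37, set test adjusted p = 2.58e-05, adjusted p = 0.389 with an estimated correlation): Vegfa rose 1.54-fold (adjusted p = 0.00381), Slc2a1 1.30-fold, and Ndrg1 fell 1.31-fold. With fry the neutrophil (0.0783) and glycolysis (0.0645) calls were lost.

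The other lists did not pass after PGE2. Adjusted over the list alone, 3 homing, 3 STAT5, 2 MHC class II, 1 megakaryocyte and 1 mast cell genes were higher, and 3 erythroid, 2 megakaryocyte and 2 BCL2 family genes lower, with the other counts the same. Set test adjusted p was 0.0809 for oxidative phosphorylation (0 of 15 called), 0.103 for MHC class II genes (0 of 7) and for unfolded protein and amino acid stress (0 of 16). The first passed without DMSO replicate 1 (0.0069) or PGE1 replicate 2 (0.0384), the second without DMSO replicate 1 (0.0207) and the third without PGE1 replicate 1 (0.0366). It was 0.312 for BCL2 family genes (1 of 14 lower), 0.322 for erythroid markers (1 of 12 lower; median 0.01, mean -0.23), 0.353 for mast cell and basophil markers (1 of 10 lower), 0.381 for megakaryocyte markers (1 of 12 lower) and 0.571 for heat shock genes (0 of 10; median 0.01, mean -0.03). Prostanoid genes (1 of 13 lower) and STAT5 targets (5 of 17 lower; median 0.07, mean -0.09) both had 0.61. Homing and adhesion genes (1 of 14 higher, 3 lower; median 0.06, mean -0.03) had 0.82, ribosomal protein genes (0 of 30) 0.827, sex-linked genes (0 of 5; median -0.07, mean 0.02) 0.874 and T and NK cell markers (1 of 4 lower; median 0.14, mean -0.08) 0.951. Among other rises by size, Thbs1 was 1.89-fold higher (699 ± 17.3 against 370 ± 20.1), a call lost without PGE2 replicate 1 (adjusted p = 0.061) or 2 (0.0556). Fn1 (1.70-fold), C5ar1 (1.78-fold), Ms4a4a (1.85-fold), Tgm2 (1.61-fold) and Klrb1f (1.68-fold) lost theirs without either of these too.

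**Figure D4:**
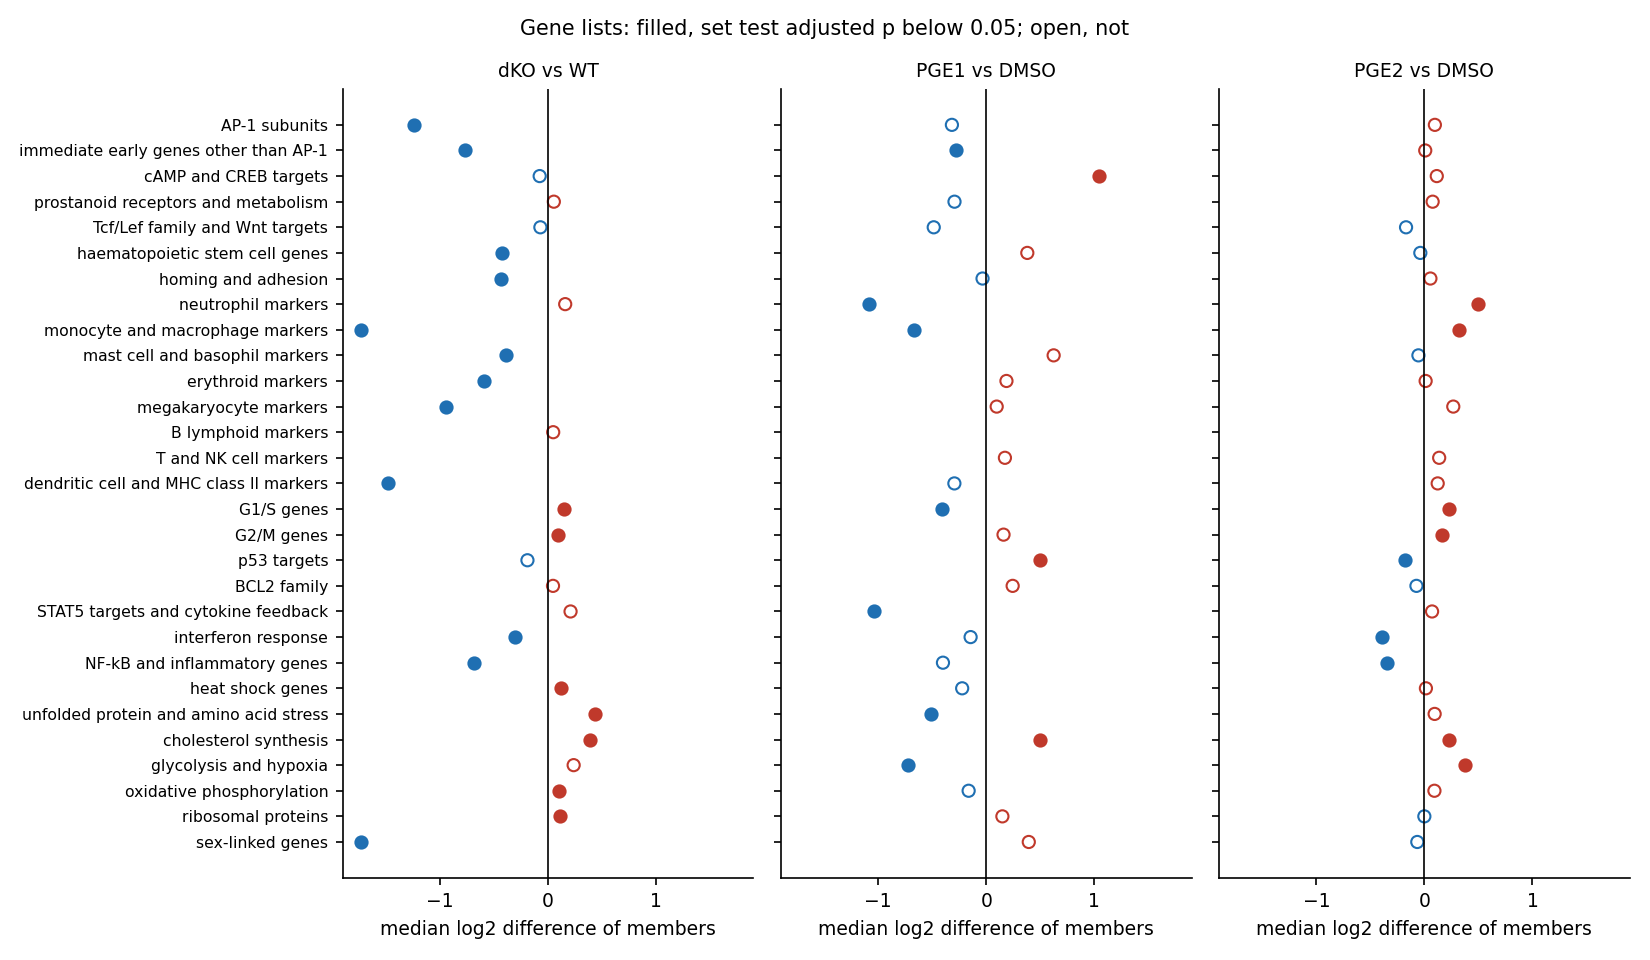
Median log2 difference of the tested members of each gene list (x axis) for dKO against WT and for PGE1 and PGE2 against DMSO; red is above 0 and blue below, filled for a set test adjusted p below 0.05 and open otherwise. Neutrophil markers stand at -1.08 after PGE1 and 0.50 after PGE2; the ribosomal, oxidative phosphorylation, G2/M and heat shock calls in dKO end with quantile normalization, where oxidative phosphorylation turns.

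PGE1 and PGE2 were compared directly at the matched dose and time. They share a prostane skeleton, and PGE2 carries an additional cis double bond in its carboxylic acid side chain. After PGE1, Tcf7 was 7.88-fold higher than after PGE2 (log2 difference 2.04, SE 0.18, adjusted p = 3.84e-05), Crem 4.73-fold (27.8 against 5.88 FPKM), Ptger2 2.99-fold (5.48 against 1.83) and Procr 4.45-fold (58.9 against 13.2). Fosb was 105-fold lower (0.841 against 88.5; log2 difference -5.60, SE 0.08), Egr1 33.4-fold (4.60 against 153; -4.80, SE 0.16) and Myc 5.75-fold (14 against 80.3). Mmp13, which fell after both, stood at 1.52 ± 0.137 and 1.64 ± 0.0657 FPKM (log2 difference -0.06, 95% interval -0.29 to 0.16).

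Of 11242 genes 6057 differed between the compounds, 3059 higher and 2998 lower after PGE1. The count was 3512 with near-identical libraries counted as 1 and 2729 with an added fold of at least 1.5. Libraries did not overlap for 7858 genes (69.9%), against 20% by chance. The 95% interval of the log2(FPKM + 1) difference, which understates low genes, lay within 1.5-fold for 5603 genes (49.8%) and 2-fold for 9172 (81.6%). Of 767 genes changed at least 2-fold after either compound, 719 differed between them and 27 had an interval within 1.5-fold. For other named genes over 10-fold lower after PGE2, the log2 difference was 0.20 (-0.04 to 0.43) for Perp. It was 0.08 (-0.33 to 0.49) for Crisp1, -0.24 (-0.56 to 0.09) for Tnfrsf11b and -1.06 (-1.30 to -0.81) for Mmp10.

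By the set test 10 lists separated the compounds. cAMP and CREB targets were higher after PGE1 in 10 of 15 cases and lower in 2, as over the list alone (median 1.10, set test adjusted p = 9.89e-04, adjusted p = 0.315 with an estimated correlation), with Pde3b 4.19-fold, Rgs2 3.66-fold (43.1 ± 6.48 against 11.8) and Pde4d 3.64-fold higher. p53 targets were higher in 11 of 13 and lower in 1, Aen, as over the list alone (median 0.62, set test adjusted p = 4.40e-04, adjusted p = 0.356 with an estimated correlation), among them Trp53inp1 (4.72-fold), Bbc3 (3.34-fold) and Mdm2 (1.56-fold). Mast cell and basophil markers were higher in 7 of 10 and lower in 1, Prss34, as over the list alone (median 0.85, set test adjusted p = 0.0158, adjusted p = 0.603 with an estimated correlation), such as Slc18a2 (5.25-fold), Cma1 (4.77-fold) and Hdc (1.89-fold). Neutrophil markers were lower after PGE1 in 17 of 18 and higher in 0, as over the list alone (median -1.54, set test adjusted p = 5.35e-07, adjusted p = 0.356 with an estimated correlation), with Ltf, lactoferrin, 4.62-fold, Fcnb 3.58-fold and Cebpa 2.95-fold lower. Of 16 monocyte and macrophage markers 12 were lower and 1 higher (13 and 1 over the list alone; median -0.77, set test adjusted p = 2.22e-04, adjusted p = 0.356 with an estimated correlation): Adgre1 was 4.82-fold and Irf8 3.23-fold lower, and Cd14 4.19-fold higher. G1/S genes were lower in 14 of 16 and higher in 0 (15 lower over the list alone; median -0.63, set test adjusted p = 3.17e-06, adjusted p = 0.46 with an estimated correlation), with Ccne1 3.48-fold and Rrm2 2.44-fold lower. STAT5 targets were lower in 15 of 17 and higher in 0, as over the list alone (median -0.67, set test adjusted p = 3.17e-06, adjusted p = 0.35 with an estimated correlation), with Socs1 5.34-fold and Cish 3.60-fold lower. Glycolysis and hypoxia genes were lower in 12 of 15 and higher in 1, Vegfa, as over the list alone (median -1.11, set test adjusted p = 2.32e-04, adjusted p = 0.603 with an estimated correlation), with Pdk1 3.62-fold, Pfkp 2.58-fold and Hk2 2.35-fold lower. Unfolded protein and amino acid stress genes were lower in 11 of 16 and higher in 3, as over the list alone (median -0.69, set test adjusted p = 0.0162, adjusted p = 0.619 with an estimated correlation), with Hspa5 2.07-fold lower and Ddit4 3.48-fold higher. Oxidative phosphorylation genes were lower in 7 of 15 and higher in 0, as over the list alone (median -0.25, set test adjusted p = 0.045, adjusted p = 0.705 with an estimated correlation), a call lost after quantile normalization (0.0811), with a minimum of 5 FPKM (0.0723), with fry (0.0931) and without PGE1 replicate 1 (0.137), PGE1 replicate 3 (0.109), PGE2 replicate 1 (0.0527) or PGE2 replicate 2 (0.0898).

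Other lists did not separate the compounds by the set test. Adjusted p was 0.15 for AP-1 subunits (1 of 10 higher, 5 lower; median -0.40), with Fosl2 3.06-fold higher and Fos 1.97-fold lower after PGE1. It was 0.216 for immediate early genes (4 of 16 higher, 9 lower; 5 and 9 over the list alone; median -0.25), with Klf2 8.30-fold lower and Dusp5 2.62-fold higher. It was 0.392 for Tcf/Lef family and Wnt target genes (2 of 7 higher, 4 lower; median -0.28), with Ccnd1 8.29-fold lower, and 0.157 for stem cell genes (11 of 19 higher, 5 lower; median 0.52), with Cd34 2.44-fold lower and Meis1 2.51-fold higher. Adjusted p lay between 0.142, for cholesterol synthesis, and 0.967, for G2/M genes, in the lists not yet named. Ribosomal protein genes passed after quantile normalization (0.0241). The median and mean differed in sign for NF-kB and inflammatory genes (0.18 and -0.05), homing and adhesion genes (-0.02 and 0.02) and megakaryocyte markers (0.01 and -0.03). Ptger3 was 2.55-fold lower after PGE1. Ptger1 was 1.24-fold higher (adjusted p = 0.00446), a call lost without PGE2 replicate 2 (0.0615), and Ptger4 1.45-fold higher (adjusted p = 0.0294), a call lost without PGE1 replicate 1 (0.054), PGE1 replicate 3 (0.0652), PGE2 replicate 1 (0.189) or PGE2 replicate 2 (0.057). By size, Ramp3 (46.5 against 3.80, 12.2-fold), Pdcd1 (18.9 against 1.15, 16.4-fold), Ccr7, a chemokine receptor (29.0 ± 2.18 against 2.47 ± 0.523, 11.7-fold), and Peg10 (43.9 against 4.35, 10.1-fold) were higher after PGE1. Mt2 was 11.1-fold higher with a wide spread (310 ± 267 against 27.9 ± 0.705, adjusted p = 0.00106; 5.57-fold without PGE1 replicate 2). Lpl (0.751 against 20.8, 27.7-fold), Prg2 (8.43 ± 9.81 against 73.8, 8.75-fold, 24.67-fold without PGE1 replicate 1) and Ms4a3 (34.4 ± 26.3 against 294 ± 1.37, 8.55-fold, 15.15-fold without PGE1 replicate 1) were lower.

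Both responses use the same DMSO libraries. Across the 11242 genes, which are not independent replicates, the log2 responses correlated at r = 0.0614 (Spearman rho = -0.2159). In 100 simulations of unchanged groups against the same DMSO libraries r averaged 0.4475. The covariance was 0.009243 against a simulated 0.01034, a difference of -0.001094. In all, 481 genes were called after both compounds, 297 of them in the same direction. Called higher after both were 47 genes, against 26.4 for independent lists, and lower after both 250, against 130.9. Of the 184 that went opposite ways, 142 were higher after PGE1 and lower after PGE2 (121.3 for independent lists) and 42 the reverse (28.5). The number of opposite genes with the direct contrast called was 17 or 9 without PGE2 replicate 1 or 2, all higher after PGE1. It was 33 or 34 without DMSO replicate 2 or 3 and 305 or 414 without PGE1 replicate 1 or 2. The 3 DMSO libraries do not give 2 for each compound, so part of the excess in the same direction may come from them. Procr was one of the opposite genes (log2 difference 1.38 after PGE1 and -0.68 after PGE2), and so was Egr1 (-4.06 and 0.74).

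**Figure D5:**
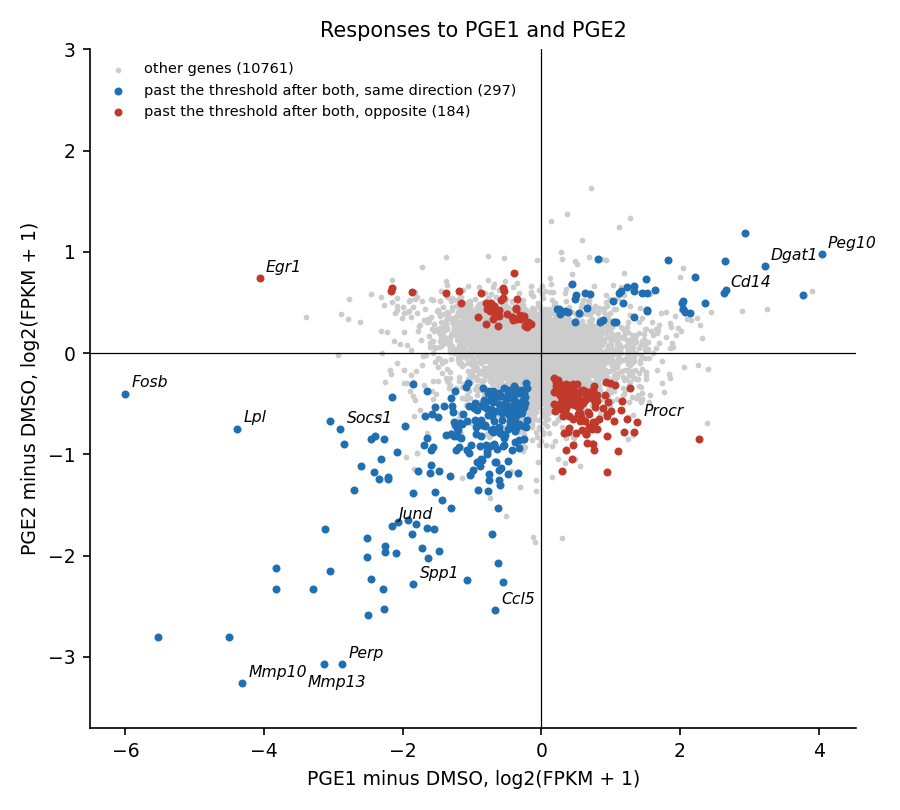
Difference from DMSO in log2(FPKM + 1) after PGE1 (x axis) and after PGE2 (y axis), 1 dot per gene for 11242 genes; blue, 297 genes past the threshold after both in the same direction; red, 184 past it in opposite directions; grey, the other 10761. Across all genes r is 0.0614.

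The last comparison asked whether either prostaglandin moved genes as loss of Tcf1 and Lef1 did. Genes higher in dKO were lower after PGE1 more often than higher: of 1893 tested, 964 fell and 166 rose, with a median of -0.26 (set test adjusted p = 7.00e-13; p = 0.129 with an estimated correlation). The median was -0.12 after quantile normalization (997 lower and 403 higher of 2688) and -0.59 with a list of 100 genes. After PGE2 their median was 0.11 (set test adjusted p = 7.00e-13; p = 0.13 with an estimated correlation), a call lost with fry (adjusted p = 0.0849). Called were 28 higher and 15 lower, 3 and 4 without DMSO replicate 2 or 3, 1 and 2 without either PGE2 library. They were 89 and 19 without PGE1 replicate 1, 117 and 25 without PGE1 replicate 2 and 47 and 25 after quantile normalization. Of 2443 genes lower in dKO, 294 were called lower and 36 higher after PGE2, against 64 to 463 and 2 to 87 with 1 library left out (median -0.09, set test adjusted p = 2.07e-08; adjusted p = 0.0901 with an estimated correlation). After PGE1 the genes lower in dKO went both ways, 862 higher and 551 lower (median 0.11, set test adjusted p = 0.00864; p = 0.191 with an estimated correlation). That last result turned with the 100 genes of smallest p as the list (median -0.52, adjusted p = 3.56e-08), and its call was lost after quantile normalization (adjusted p = 0.166) and without WT replicate 1 (0.0512), WT replicate 3 (0.0671) or dKO replicate 3 (0.0640). Fosb, Egr1, Jund and Ccnd1 were among the genes lower both in dKO and after PGE1. Across genes the dKO difference correlated with the PGE1 response at r = 0.0056 and with the PGE2 response at r = 0.2938. Among the 10566 genes tested in both sets of libraries, 294 were lower both in dKO and after PGE2, against 94.3 for independent lists, and 28 higher in both, against 19. The pairs of opposite direction, higher or lower in dKO, held 15 and 36 (73.1 and 24.5 for independent lists). For PGE1, 551 were lower in both, against 634.2, and 166 higher, against 430.3, while those of opposite direction held 964 and 862 (491.4 and 555.4). The sets share no library, and the sex-linked difference of the dKO libraries is part of each of these lists.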

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

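All results here come from the planned contrasts of PGE1 and PGE2 with DMSO and with each other; picking the lists that went opposite ways followed from their values. After PGE1 and after PGE2, 184 genes moved away from DMSO in opposite directions, with the direct contrast past the threshold for each (limma, adjusted p below 0.05). Of these, 142 were higher after PGE1 and lower after PGE2, and 42 were the reverse. These counts rested on single libraries: they were 17 and 0 or 9 and 0 without PGE2 replicate 1 or 2, 29 and 4 or 30 and 4 without DMSO replicate 2 or 3, and 174 and 131 or 263 and 151 without PGE1 replicate 1 or 2.

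With the preset correlation, 5 gene lists passed the set test in opposite directions after the 2 compounds and in the direct contrast. With an estimated correlation none of the 5 passed after PGE1 (adjusted p from 0.383 to 0.508), after PGE2 (0.303 to 0.389) or in the direct contrast (0.356 to 0.603). With fry the neutrophil (0.0783) and glycolysis (0.0645) lists did not pass after PGE2. Neutrophil markers had a median of -1.08 after PGE1 and 0.50 after PGE2, with a median difference of -1.54 (adjusted p = 5.35e-07). Monocyte and macrophage markers stood at -0.67 and 0.32, with a difference of -0.77 (adjusted p = 2.22e-04). G1/S genes stood at -0.41 and 0.23, with a difference of -0.63 (adjusted p = 3.17e-06). p53 targets stood at 0.50 and -0.18, with a difference of 0.62 (adjusted p = 4.40e-04). Glycolysis and hypoxia genes stood at -0.72 and 0.37, with a difference of -1.11 (adjusted p = 2.32e-04).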

How the results depend on the processing

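The fits on recovered reads and on averaged libraries were chosen after seeing the data; all other settings here were fixed earlier. Averaging near-identical libraries leaves fewer samples, and an added fold of at least 1.5 leaves fewer genes by construction. Where no such reason is given, the cause was not tested.

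For dKO against WT, 4381 genes were called. The count was 768 with the WT libraries averaged and 880 with the added fold, and lay within 1.5 times of 4381 under every other setting run, from 3053 to 5277 with 1 library left out. For PGE1 against DMSO, 5515 genes were called, 2092 with the added fold and 4534 to 6126 with 1 library left out. No other setting moved that count by over 1.5 times. For PGE1 against PGE2, 6057 genes were called. The count was 3512 with libraries averaged, 2729 with the added fold and 4253 to 6653 with 1 library left out, and the other settings stayed within 1.5 times.

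PGE2 against DMSO was the least stable. Its 626 genes became 3794 with library weights, 1207 with all 14 libraries in the fit, 297 with the added fold and 55 with libraries averaged. Leaving out 1 library gave 125 (without PGE2 replicate 2) to 1218 (without PGE1 replicate 2), and limma-voom on recovered reads gave 784. Of the 54 named genes called there, 41 lost the call with libraries averaged. Of the named genes with a value under averaging, 28 of 94 called in dKO against WT, 2 of 73 after PGE1 and 7 of 67 in PGE1 against PGE2 did so.

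With the replicate number as a block, 269 genes were called for PGE2 against DMSO, 3972 for dKO against WT, 5191 for PGE1 against DMSO and 5313 for PGE1 against PGE2, and the 184 opposite genes were 44 (38 and 6). The numbers did not pair the libraries: deviations of same-numbered libraries correlated at 0.038, 0.117 and 0.002 for WT and dKO, at -0.141, -0.249 and 0.253 for DMSO and PGE1, and at -0.072 and -0.075 for DMSO and PGE2. DMSO replicate 1 correlated best with PGE1 replicate 2 (0.409). Under the block 23 of the 54 PGE2 named genes lost their call, as did 3 of 98 for dKO and 1 of 68 for PGE1 against PGE2. Among lists, the block ended the oxidative phosphorylation call in PGE1 against PGE2 (adjusted p = 0.0934) and brought STAT5 targets (0.0472) and glycolysis (0.022) in dKO past the threshold.

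Tcf7 was below the minimum level in the untreated fit, so its difference of -1.07 had no limma test there. It was -2.88 with a pseudocount of 0.1 and -0.31 with 5, a move that follows from the low level. With no filter, and with all 14 libraries in the fit, it was -1.07 and passed (adjusted p = 2.92e-04 and 6.19e-05). Depth limits Tcf7 and Lef1, with 26 and 54 reads over the dKO libraries. Rpl8 turned to -0.231 in dKO after quantile normalization.

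With an estimated correlation the number of lists that passed was 0 in each of the 4 comparisons, against 19, 10, 9 and 10 with the preset one. With fry it was 26, 24, 8 and 21; the calls ended were those of neutrophil (0.0783) and glycolysis genes (0.0645) after PGE2 and of oxidative phosphorylation in PGE1 against PGE2 (0.0931). In dKO against WT the direction of fry was down against a set test that was up for prostanoid genes (median 0.0537), B lymphoid markers (0.0477) and BCL2 family genes (0.046). The set test of oxidative phosphorylation turned after quantile normalization (median 0.0098).

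Genes higher in dKO kept their medians with an estimated correlation but not their calls, -0.258 after PGE1 and 0.1114 after PGE2 (adjusted p = 0.173 for both), and the latter lost its call with fry (0.1114, adjusted p = 0.0849). Genes lower in dKO did likewise after PGE2 (-0.0876, adjusted p = 0.0901). After PGE1 the latter genes had a median of 0.1144 (adjusted p = 0.191) with an estimated correlation, 0.0957 after quantile normalization, -0.5213 as a list of 100 and 0.0915 to 0.128 with 1 library left out. The correlation of both responses, 0.0614, was 0.1398 with a pseudocount of 0.1, -0.0193 with a minimum of 5 FPKM, 0.0858 after quantile normalization and 0.0371 to 0.0824 with 1 library left out.

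Over single named genes and all settings, 6049 results kept direction and side of the threshold, 317 lost the call, 79 gained it, 4 moved without a call and 1, Rpl8, turned. For gene lists these numbers were 1343, 65, 53, 32 and 4. The alternative for repeated symbols was not run, as 0 were repeated. Other splits of the 6 libraries were counted for both comparisons of 3 against 3. In each, 1 of 10 splits, the real one, called as many genes (4381 and 5515, against at most 0 in any other), and 10 splits are too few for a share under 0.05.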

Other observations

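The comparison of DMSO with untreated WT cells and its named genes were chosen after the data were seen, as were the tests below on immediate early genes and on lineage markers; both tests on the PGE2 response were written before their results. Control LSCs after 6 h in DMSO were set against untreated WT LSCs. Spp1, osteopontin, was 14.4-fold higher after DMSO (637 ± 5.46 against 44.3 ± 1.75 FPKM; SD, n = 3 each), Hmox1, heme oxygenase, 9.58-fold (193 ± 9.36 against 20.1 ± 0.641) and Nqo1, a quinone reductase, 14.9-fold (19.7 against 1.33). Procr went from 1.01 to 21.8 FPKM, Mmp10 from 0.872 to 19.9 and Cxcl3 from 5.03 to 60.6. Prg3 was lower, at 3.85 against 13.3 FPKM, as was Epx, at 3.54 against 9.91. So were Flt3, at 2.44 against 5.50, and Mpo, the myeloperoxidase of granulocyte progenitors, at 1331 against 2499. With all 14 libraries in 1 limma fit, 5415 of 11078 genes were called, 2526 higher and 2889 lower; 291 were over 2-fold higher and 6 over 2-fold lower. Vehicle, further culture and library depth differ together between these groups.

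NF-kB and inflammatory genes were higher after DMSO in 18 of 19 cases (median 0.91, set test adjusted p = 2.89e-10, adjusted p = 0.113 with an estimated correlation) and interferon-response genes in 17 of 19 (median 0.74, adjusted p = 6.25e-09; 0.0699 with an estimated correlation). p53 targets were higher in 6 of 13 (adjusted p = 0.00161; 0.136 with an estimated correlation), and immediate early genes in 9 of 16 with 3 lower (adjusted p = 0.0407; 0.765 with an estimated correlation). G1/S genes were lower in 16 of 16 (median -0.45, adjusted p = 6.98e-08; 0.194 with an estimated correlation) and G2/M genes in 13 of 16 (median -0.35, adjusted p = 8.23e-06; 0.113 with an estimated correlation). Oxidative phosphorylation genes were lower in 12 of 15 (adjusted p = 6.44e-04; 0.758 with an estimated correlation). Ribosomal protein (7 of 30 lower) and cholesterol synthesis genes (7 of 17 lower) passed at adjusted p = 0.0231 and 0.0485, each with 0.765 with an estimated correlation. No other list passed.

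The PGE2 response ran against this difference: of the 291 genes, 278 were lower after PGE2 than after DMSO, by a median share of 0.52 of the difference, against 171 and 0.186 after PGE1. Across genes the correlation of the PGE2 response with the DMSO minus WT difference was -0.794, and that of the PGE1 response 0.14. The DMSO libraries enter both with opposite signs, but with separate DMSO libraries on each side the correlation was -0.692, and -0.572 with these exchanged, which argues against shared libraries as the whole cause. Of 626 genes called, 111 (17.7%, bounds set at 5% and 20%) had both PGE2 libraries outside the range of all WT and DMSO libraries. This share lay between the bounds, so a mix of untreated and DMSO cells stays open. How many genes would leave that range through spread between libraries alone was not tested. An action of PGE2 on culture-induced genes may also account for the pattern (not tested).

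Fosb and Egr1 fell both in dKO and after PGE1. Handling before lysis that raised the immediate early response in 1 group could lower all such genes in the other. In dKO the other 24 tested AP-1 and immediate early genes had a median of -0.85 (lower quartile -1.25) and Fos fell with them, so handling stays open beside the genotype. After PGE1 the median of those 24 was -0.26 (lower quartile -0.77). Fos did not pass (114 against 118 FPKM, adjusted p = 0.707), but most immediate early genes fell. Handling and an untested PGE1 effect stay open.

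Marker lists of 5 lineages passed as lower in dKO although the sort took lineage-negative cells; the neutrophil and B lymphoid lists did not pass. A lower share of the sorted type in WT stays open: other cells need not raise lists alike. Medians of 6 lineage lists (not neutrophil) spanned 1.78 log2 units (permutation p = 0.00435, 100000 gene exchanges, too small where list genes correlate). Fewer monocyte-lineage cells among dKO cells should lower Ly6c2, F13a1 and Irf8 by the monocyte list's -1.73. Their median missed this at -0.46, with Ly6c2 at 346 against 336 FPKM (adjusted p = 0.726). Early progenitors carry them too, so this cause stays open. A lower level per cell, not tested, stays open too. Genotype and the sex-linked difference were not tested apart.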
